A study of Homo sapiens with 9 samples.

How the data were processed

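RNA was measured in 9 libraries of the human cell line OCI-AML-3, 3 from the parental line, 3 from knockout clone 1 and 3 from knockout clone 2, each group described by the labels' protocols as 3 biological replicates. The labels' protocols give the same text for all 9 libraries, name total RNA, ribosomal RNA depletion and an mRNA preparation kit together, and name 2 sequencers without saying which library ran on which. Library preparation or sequencer can therefore follow the groups, and the tests cannot separate them. The submitters' processing notes name Subread, featureCounts, DESeq2 1.26.0 and the GRCh38 build without saying what each was used for. The settings of alignment and the version of the gene annotation are not given in the sources used here.

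The authors deposited a table of RPKM per gene and library, with gene positions and exons per the file headers, a log2 fold change of all 6 knockout libraries against WT and its p-value and adjusted p-value. RPKM divides each gene's reads by its exonic length and by the library's total of reads in genes, so a few abundant RNAs lower every other gene of a library. Multiplying back by length and total gave whole reads for 100% of values within 1e-06 of a read, so no rounding or offset was found. Of 28279 lines 2 were left out as 1 record broken over 2 lines, which left 28277 genes. Among them 5914 had no reads in any library, 2 had names in the form of a date and 0 were mitochondrial genes. Exonic bases were shared with another gene in 6341 genes, and MALAT1 and its antisense TALAM1 had 99192 and 97456 reads in WT, so reads were counted without regard to strand. A GENCODE 29 gene of the same name was found for 25558 genes, of which 25517 overlapped it, and 95.5% had a RefSeq symbol.

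In the authors' deposited table each of the 15973 p-values equals, within 1e-06, the unequal-variance comparison of log2(RPKM + 1) between the WT and all knockout libraries. By the authors' deposited adjusted p-value 1 gene passed 0.05, B4GALNT3, with a log2 fold change of -1.51 and an adjusted p of 0.000382, and H1-3 stood at 4.22 with an adjusted p of 0.360. These columns were not used in the tests.

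The tests used limma 3.58.1 in R 4.3.3, with GenomicRanges 1.54.1, the data.table package (version 1.17.8) and, for the figures, matplotlib 3.10.9 and pandas 2.3.3. The design had named a count model first and this test for the case that the table held RPKM. Since the deposited unit is RPKM, log2(RPKM + 0.1) was fitted with a mean-variance trend, with 1 coefficient per group over all 9 libraries, in genes with at least 0.5 RPKM in at least 3 libraries, which left 15111. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and the p-values measure only the spread between these samples. The comparisons were each clone against WT, both clones in the same direction, the mean of both clones against WT, and clone 2 against clone 1. They were chosen, with the tests, gene lists and alternatives, before the data were examined.

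Of 29 fixed gene lists 28 were tested, since none of the mitochondrially encoded mRNAs is present. Camera in limma was run with a preset correlation of 0.01 between genes and again with an estimated one, adjusted over the lists, and list members were counted adjusted over all genes and over the list alone. The text names H1-3 and the other linker histone genes; up to 12 genes per direction changed in both clones with a mean of at least 1 RPKM, of which there were 5 in all; the 8 highest and 8 lowest between clones with the same minimum; and up to 4 members of a list with the smallest adjusted p. Genes with clone-based or systematic names were not named by this rule, and some results for genes it names are not reported here. Genes outside it are said to have been chosen after their values were seen. For genes with few reads, reads were pooled per group and compared with a 95% exact binomial interval. A gene with 0 reads in a group is given a bound of 3 reads over the group. Intervals and floors cover counting error only.

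Reads in genes were 29889102, 30273538 and 30408431 in WT, 15042779, 12692130 and 14886086 in clone 1 and 26915646, 15789001 and 21641595 in clone 2. Correlations of log2 values were 0.976 to 0.979 within WT, 0.914 to 0.958 within clone 1, 0.969 to 0.977 within clone 2, 0.947 to 0.974 between WT and clone 2 and 0.806 to 0.855 between WT and clone 1. Genes named for ribosomal RNA held 26.8%, 5.28% and 2.29% of reads in the clone 1 libraries, 4.93% in WT replicate 2 and 0.193% to 0.454% in the other 5. The text writes of libraries labelled clone 1 because H1-3 was higher there than in WT. Other histone mRNAs were higher there too, so this level does not say whether the label is right. No library was left out of the tests.

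The tests were tried on simulated data with 100 genes changed 4-fold and 100 changed 2-fold between groups of the depth of WT and clone 2. The fit of all libraries recovered 89 and 34 of them with 6.11% false calls, and the fit of WT and clone 2 alone recovered 90 and 61 with 11.7% false calls. Alternatives covered scaling by median of ratios, limma-voom on the recovered reads, no filter and a stricter filter (a CPM of 1 in 3 libraries and 10 reads), a replicate block, a fit of only the groups compared, a pseudocount of 1, a 2-fold minimum, each library left out in turn, and, chosen after the data were seen, a fit without WT replicate 2 and clone 1 replicate 1. The scan for neighbouring genes took medians over windows of 8 genes and compared them with 1000 random orders. Splits of the libraries were counted in full for groups of 3 against 3 and as 100 drawn splits otherwise. Sequence reads, DNA copy number and protein levels were not analysed here.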

Results

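Gene expression was measured by RNA sequencing in OCI-AML-3, a human acute myeloid leukaemia cell line, and in 2 derived lines in which the gene of linker histone H1.3, H1-3, was edited to knock it out. Linker histones bind the nucleosome where DNA enters and leaves it. The 9 libraries formed 3 groups of 3 biological replicates, wild type (WT), knockout clone 1 and knockout clone 2. Reads assigned to genes ranged from 29889102 to 30408431 per WT library, from 12692130 to 15042779 per library labelled clone 1, and from 15789001 to 26915646 per clone 2 library. Expression was analysed on the deposited RPKM scale (reads scaled to gene length and to the total of the library), and 15111 genes were tested. Values below are log2 fold changes with their standard error (SE), or mean RPKM ± SD with n = 3 libraries per group.

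The first comparison asked whether H1-3 itself was lower in the knockout lines. H1-3 (chromosome 6, 26234212 to 26234988, GRCh38) stood at 1.25 ± 0.995 RPKM in WT, 0.213 ± 0.105 in clone 2 and 81.8 ± 12.1 in the libraries labelled clone 1 (SD, n = 3). Clone 2 held 10 H1-3 reads in all against 88 in WT, a ratio of 0.160 after scaling to depth, with a 95% counting interval of 0.0741 to 0.308. WT replicate 2 held 56 of the 88 reads, and without it the ratio was 0.293, with an interval of 0.128 to 0.611. In the test across all genes the clone 2 change of -1.92 (SE 0.48) did not pass (limma adjusted p = 0.280), and it was -0.81 with a pseudocount of 1. In the libraries labelled clone 1 H1-3 was not lower, with 2735 reads and a level that rose by 6.17 (SE 0.48, limma adjusted p = 5.54e-05). Other histone mRNAs rose there by a like amount, as given below, so this level does not bear on the label. An edit that disrupts the protein need not lower its mRNA, so the level alone does not say whether the gene was knocked out.

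The other linker histone genes whose mRNAs are made in S phase moved with H1-3 in the libraries labelled clone 1. H1-2 rose by 6.16 (SE 0.38, limma adjusted p = 2.21e-05), H1-4 by 7.84 (SE 0.70, limma adjusted p = 0.000118) and H1-5 by 7.47 (SE 0.64, limma adjusted p = 9.46e-05). Of the mRNA of H1-2, H1-3, H1-4 and H1-5 together, H1-3 made up 6.42%, 8.88% and 9.86% in the WT libraries, 2.67%, 5.34% and 7.81% in those labelled clone 1, and 1.31%, 2.14% and 3.63% in clone 2. H1-10, a linker histone made outside S phase as well, fell in the libraries labelled clone 1 with a change of -1.05 (SE 0.34, limma adjusted p = 0.0416), a call that was lost without any 1 of the 3 WT or 3 clone 2 libraries (limma adjusted p up to 0.115, without WT replicate 3), without a filter on low values or with only the 2 groups compared (0.0586 and 0.0788 in limma). H1-10 stood at -0.60 without clone 1 replicate 1. In clone 2 none of H1-2, H1-4, H1-5 and H1-10 passed. The clone 2 values were 0.34 (SE 0.38) for H1-2, -1.78 (SE 0.70) for H1-4, -1.86 (SE 0.64) for H1-5 and -0.02 (SE 0.34) for H1-10. H1-3, at -1.92 in clone 2, thus moved by a like amount to H1-4 and H1-5. Its lower share there goes with H1-2, which did not fall, so a change particular to H1-3 is not shown. Without WT replicate 2 H1-2 stood at 0.66, H1-4 at -1.03 and H1-5 at -1.14. H1-2 stood at 0.08 without clone 2 replicate 2. H1-4 stood at -1.18 and H1-5 at -1.19 with a pseudocount of 1.

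**Figure D1:**
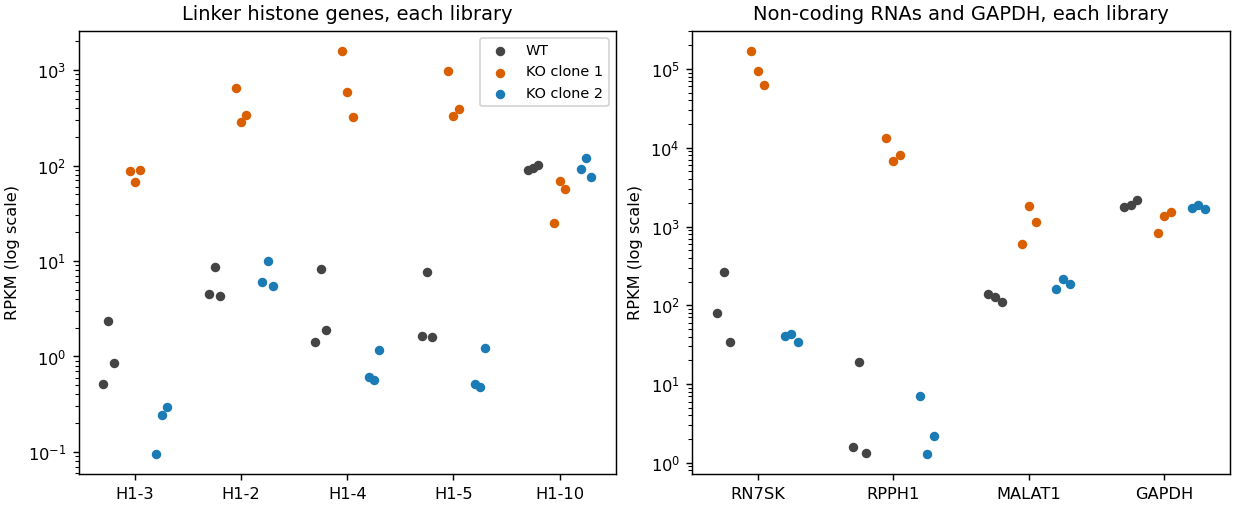
Expression in RPKM (logarithmic axis) of 5 linker histone genes on the left and of the non-coding RNAs RN7SK, RPPH1 and MALAT1 with GAPDH on the right, 1 point per library in WT, clone 1 and clone 2. H1-3 lies at 0.517 to 2.38 in WT, 67.9 to 90.0 in the libraries labelled clone 1 and 0.0956 to 0.297 in clone 2.

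Clone 1 against WT asked which genes changed in the first knockout line. In the libraries labelled clone 1, core histone mRNAs and abundant non-coding RNAs were raised. All 53 replication-dependent core histone genes tested rose, by a median of 6.93 (limma camera adjusted p = 1.78e-48; adjusted p = 0.179 with an estimated correlation). H2BC21 rose by 5.63 (SE 0.29, limma adjusted p = 9.84e-06) and H3C10 by 7.60 (SE 0.39, limma adjusted p = 9.84e-06). Of 12 abundant non-coding RNAs 11 rose, by a median of 8.15 over the list (limma camera adjusted p = 5.87e-12; adjusted p = 0.179 with an estimated correlation). Among them, TERC, the RNA of telomerase, rose by 7.68 (SE 0.42, limma adjusted p = 1.19e-05), RN7SK, which holds back the elongation factor P-TEFb, by 10.12 (SE 0.63, limma adjusted p = 2.27e-05), and RPPH1, the RNA of ribonuclease P, by 11.29 (SE 0.94, limma adjusted p = 8.17e-05). RN7SK reached 167525, 94682 and 62876 RPKM in these 3 libraries against 34.5 to 263 RPKM in WT and 33.8 to 43.3 RPKM in clone 2. Core histone genes took 0.396% to 0.870% of reads there, 0.00392% to 0.00926% in WT and 0.00671% to 0.00996% in clone 2.

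Mitosis genes were lower in each library labelled clone 1, and S phase genes, on the deposited scale, mainly in clone 1 replicates 1 and 2. Of 52 genes of G2/M and mitosis 48 fell and none rose, with a median of -1.12 (limma camera adjusted p = 2.14e-16; adjusted p = 0.527 with an estimated correlation). CKS1B, which binds cyclin-dependent kinases, fell with a change of -1.56 (SE 0.16, limma adjusted p = 0.000208), CCNB1, the mitotic cyclin B1, with -1.81 (SE 0.18, limma adjusted p = 0.000224), and CDC20, which activates the anaphase-promoting complex, with -2.32 (SE 0.25, limma adjusted p = 0.000281). Of 50 genes of DNA replication and S phase 25 fell and 1 rose, with a median of -0.87 (limma camera adjusted p = 9.62e-07; adjusted p = 0.834 with an estimated correlation). The S phase means, centred on WT, were -1.12, -0.99 and -0.27 in clone 1 replicates 1, 2 and 3. WT replicate 1 stood at -0.28, so on this scale clone 1 replicate 3 lay at the level of a WT library. These means were not rescaled. The median-of-ratios factor, low where most genes read low, was 0.664, 1.03 and 1.11 in clone 1 replicates 1, 2 and 3. In WT it was 0.986 to 1.04. The low S phase mean of clone 1 replicate 1 can therefore come in part from scaling. PCNA, the sliding clamp of DNA polymerases, fell with a change of -1.53 (SE 0.26, limma adjusted p = 0.00271) and TYMS, thymidylate synthase, with -1.55 (SE 0.27, limma adjusted p = 0.00287). SLBP, which binds the 3' end of histone mRNAs, fell with a change of -0.78 (SE 0.16, limma adjusted p = 0.00550). Adjusted over the list alone, 50 mitosis genes and 34 S phase genes fell.

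Metabolic and growth genes fell beside them. Of 23 cholesterol biosynthesis genes 17 fell, with a median of -1.24 (limma camera adjusted p = 4.13e-07; adjusted p = 0.584 with an estimated correlation). ACAT2 fell with a change of -1.84 (SE 0.23, limma adjusted p = 0.000646), and FDFT1, squalene synthase, with -1.14 (SE 0.15, limma adjusted p = 0.000912). Of 28 nuclear genes of oxidative phosphorylation 19 fell, with a median of -0.72 (limma camera adjusted p = 9.62e-07; adjusted p = 0.562 with an estimated correlation). ATP5F1A, a subunit of ATP synthase, fell with a change of -1.23 (SE 0.14, limma adjusted p = 0.000460). Of 35 MYC and ribosome biogenesis genes 20 fell and 1 rose, with a median of -0.69 (limma camera adjusted p = 7.64e-06; adjusted p = 0.527 with an estimated correlation). NIP7, a ribosome assembly factor, fell with a change of -1.26 (SE 0.16, limma adjusted p = 0.000597) and ODC1, the first enzyme of polyamine synthesis, with -1.71 (SE 0.28, limma adjusted p = 0.00197). Adjusted over each list alone, 18, 22 and 23 genes fell.

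Interferon-stimulated genes were higher as a group in the libraries labelled clone 1, on the deposited scale in 2 of the 3. Of 40 tested, 5 rose and 1 fell, 33 lay above 0, and the median was 0.46 (limma camera adjusted p = 0.00238; adjusted p = 0.834 with an estimated correlation). The mean of the list, centred on WT, was -0.04, 0.94 and 0.53 in clone 1 replicates 1, 2 and 3 and -0.18 to 0.13 in WT. These means were not rescaled either. With a median-of-ratios factor of 0.664 in clone 1 replicate 1, its lower mean can come from scaling. The median was 0.75 without clone 1 replicate 1 and 0.30 without clone 1 replicate 2. IFI6 rose by 1.43 (SE 0.26, limma adjusted p = 0.00355) and IFITM3 by 0.78 (SE 0.17, limma adjusted p = 0.00877), while BST2, the surface protein tetherin, fell with a change of -1.43 (SE 0.26, limma adjusted p = 0.00352). Replacement histone variants fell in 7 of 10 genes and rose in 1, with a median of -0.90 (limma camera adjusted p = 0.0124; adjusted p = 0.556 with an estimated correlation), a call lost without clone 1 replicate 3 (limma camera adjusted p = 0.0514). H2AZ1 fell with a change of -1.63 (SE 0.16, limma adjusted p = 0.000180). H2BU1, which the fixed list counts here, rose by 6.44 (SE 0.61, limma adjusted p = 0.000149), close to the core histone median of 6.93 rather than to this list. The linker histones as a list rose, with a median of 6.17, or 2.82 without a filter on low values (limma camera adjusted p = 0.000220; adjusted p = 0.179 with an estimated correlation).

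In total 4707 genes passed between the libraries labelled clone 1 and WT, 1882 higher and 2825 lower. The median of all genes was -0.14 there and moved to 0.01 with median-of-ratios scaling, under which 53.3% of 5748 called genes were higher instead of 40.0%. With that scaling the medians were -0.96 for mitosis, -0.71 for S phase, -1.08 for cholesterol biosynthesis, -0.56 for oxidative phosphorylation, -0.53 for ribosome biogenesis, 0.61 for interferon-stimulated genes and 7.08 for core histones. The count moved by over 1.5 times without 1 library, to 3078, 2997 and 3111 genes without WT replicate 1, 2 or 3 and to 7252 without clone 1 replicate 1, which held 26.8% of its reads in genes named for ribosomal RNA. In the fit of all 9 libraries the 3 groups share 1 estimate of the spread. With only the 2 groups compared the count was 3235.

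Clone 2 against WT asked the same of the second line, whose H1-3 reads were below WT. Interferon-stimulated genes were higher and mitosis and S phase genes lower as groups in clone 2. Of 40 interferon-stimulated genes 39 lay above 0, with a median of 1.25 (limma camera adjusted p = 4.39e-31; adjusted p = 0.315 with an estimated correlation); 1 passed singly over all genes and 32 over the list alone. IFITM3, which blocks viral entry, rose by 1.38 (SE 0.17, limma adjusted p = 0.0201). SAMD9L, an antiviral factor, stood at 2.60 (SE 0.39, limma adjusted p = 0.0535), IFI6 at 1.71 (SE 0.26, limma adjusted p = 0.0622) and OAS2, a sensor of double-stranded RNA, at 2.45 (SE 0.42, limma adjusted p = 0.103). All 52 mitosis genes lay below 0, with a median of -0.56 (limma camera adjusted p = 1.24e-33; adjusted p = 0.315 with an estimated correlation), none past the test over all genes and 20 over the list alone. UBE2S, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, stood at -0.90 (SE 0.16, limma adjusted p = 0.105), the kinase PLK1 at -0.96 (SE 0.20, limma adjusted p = 0.185) and CDC20 at -1.13 (SE 0.25, limma adjusted p = 0.203). The IFITM3 call was lost without WT replicate 2 or 3 or any 1 clone 2 library (limma adjusted p up to 0.153, without clone 2 replicate 2).

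Clone 2 replicate 3 lay nearest to WT in the mitosis and S phase lists. The mitosis means, centred on WT, were -0.70, -0.85 and -0.15 in clone 2 replicates 1, 2 and 3 and -0.04 to 0.04 in WT. Those of S phase were -0.41, -0.72 and -0.22 in clone 2 and -0.28, 0.14 and 0.14 in WT. All 50 S phase genes lay below 0 in clone 2, with a median of -0.42 (limma camera adjusted p = 1.74e-17; adjusted p = 0.7 with an estimated correlation), none past the test over all genes or over the list alone. CDT1, which licenses replication origins, stood at -0.60 (SE 0.18), MCM7, a subunit of the replicative helicase, at -0.74 (SE 0.23) and TK1, thymidine kinase, at -0.83 (SE 0.30). Of 35 MYC and ribosome biogenesis genes 33 lay below 0, with a median of -0.24 (limma camera adjusted p = 6.7e-10; adjusted p = 0.315 with an estimated correlation), again none singly. FBL, the methyltransferase fibrillarin, stood at -0.63 (SE 0.18). Of 29 targets of the tumour suppressor p53, 28 lay above 0, with a median of 0.35 (limma camera adjusted p = 1.03e-05; adjusted p = 0.7 with an estimated correlation), none past the test over all genes and 2 over the list alone. TP53INP1 stood at 1.53 (SE 0.32), ZMAT3 at 1.09 (SE 0.27) and MDM2, the ubiquitin ligase of p53, at 0.82 (SE 0.26).

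Monocyte and macrophage markers lay above 0 in 25 of 30 genes, with a median of 0.58 (limma camera adjusted p = 0.000156; adjusted p = 0.7 with an estimated correlation), 2 of them past the test over the list alone. Without a filter the median was 0.38. The means of this list, centred on WT, were 0.59, 0.70 and 0.21 in clone 2 replicates 1, 2 and 3. They were 0.41, -0.22 and -0.19 in the WT libraries, so the groups overlapped. MS4A7 stood at 1.19 (SE 0.27) and CD36, a scavenger receptor, at 1.17 (SE 0.27). Core histone genes lay below 0 in 41 of 53 in clone 2, with a median of -0.72 (limma camera adjusted p = 4.08e-07; adjusted p = 0.7 with an estimated correlation), or -0.83 without the 6 genes that had at most 3 reads in both groups and with 1 gene at its bound. This rested on WT replicate 2, whose core histone mean centred on WT was 1.00 against -0.57 and -0.42 in the other WT libraries and -0.61 to -0.45 in clone 2. Without it the median was -0.10 and the call was lost (limma camera adjusted p = 0.278). With a pseudocount of 1 the median was -0.30. H2AC6 stood at 2.33 (SE 0.51) and H2BC12 at 1.51 (SE 0.35). Genes of DNA damage response (-0.23; limma camera adjusted p = 0.000117; adjusted p = 0.7 with an estimated correlation) and of heterochromatin and DNA methylation (-0.17; limma camera adjusted p = 0.00505; adjusted p = 0.806 with an estimated correlation) were lower as groups. The heterochromatin call was lost without WT replicate 3 (-0.06, limma camera adjusted p = 0.0971), and the DNA damage median was -0.09 without clone 2 replicate 2. HMGA1, an architectural chromatin protein, stood at -0.85 (SE 0.18) and DNMT1, the maintenance DNA methyltransferase, at -0.48 (SE 0.18).

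Heat shock and unfolded protein genes passed downward in clone 2 (limma camera adjusted p = 0.0253; adjusted p = 0.315 with an estimated correlation) although their median was 0.05 and their mean -0.03. HSPA1B, an inducible chaperone, stood at -1.11 (SE 0.36), and at -0.74 without clone 2 replicate 2. Genes of oxidative phosphorylation had a median of -0.07 (limma camera adjusted p = 0.0468; adjusted p = 0.866 with an estimated correlation), with CYC1 at -0.26 (SE 0.13). Both calls ended in the fit of WT and clone 2 alone (limma camera adjusted p = 0.0776 and 0.0676), that of heat shock also with median-of-ratios scaling (0.0701 in limma) and that of oxidative phosphorylation also with limma-voom and with a replicate block (0.0536 and 0.0592 in limma). The heat shock call was lost without WT replicate 1 or clone 2 replicate 1 (limma camera adjusted p = 0.0519 and 0.112). Its median ranged from -0.17 without clone 2 replicate 2 to 0.11 without clone 2 replicate 3. That of oxidative phosphorylation was lost without WT replicate 1 or 2, clone 1 replicate 1 or clone 2 replicate 2 (limma camera adjusted p = 0.314, 0.278, 0.0675 and 0.408). Its median ranged from -0.22 without WT replicate 3 to -0.00 without WT replicate 1.

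In total 18 genes passed between clone 2 and WT, 7 higher and 11 lower, with 1237 at an unadjusted p under 0.05. In a fit of these 6 libraries alone, without those labelled clone 1, 207 genes passed, 144 higher and 63 lower. The genes with the largest changes in that fit were named after their values were seen. They included NKD2, an inhibitor of Wnt signalling, at 3.24, IFI44 at 3.19 and FGL2 at 2.25 among those that rose, and CD9, a tetraspanin, at -2.23, WLS, which carries Wnt proteins to the cell surface, at -1.86 and TERT, the catalytic subunit of telomerase, at -1.52 among those that fell. In the fit of all 9 libraries with a pseudocount of 1 IFI44 stood at 1.41, CD9 at -1.20 and WLS at -1.15. By list, 14 interferon-stimulated genes, 4 p53 targets, 2 monocyte markers, 3 genes of the G1 list, 1 Polycomb gene and 1 neutrophil gene rose in it, and 1 mitosis, 1 S phase and 1 heterochromatin gene fell. The count of 18 was 5, 4 and 3 without WT replicate 1, 2 or 3, 7, 6 and 6 without clone 2 replicate 1, 2 or 3, and 243 without clone 1 replicate 1. With median-of-ratios scaling 68 genes passed, of which 63.2% were higher instead of 38.9%.

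**Figure D2:**
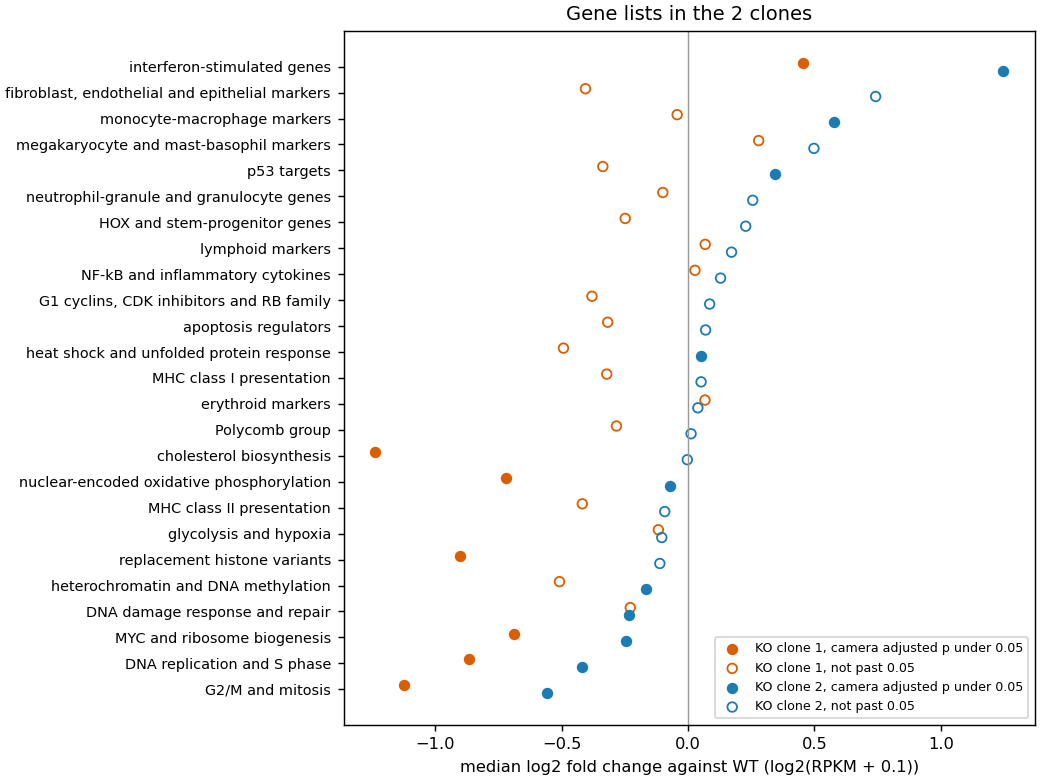
Median log2 fold change against WT of the fixed gene lists in clone 1 and clone 2, 1 point per list and clone, filled where limma camera passed at an adjusted p of 0.05 with a preset correlation; lists with a clone 1 median of 4 or more (linker histones, core histones, non-coding RNAs) are left out. Interferon-stimulated genes lie at 0.46 and 1.25, mitosis genes at -1.12 and -0.56.

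The central question was which genes changed in both knockout lines in the same direction. In both, 9 genes did, 3 higher and 6 lower. The balance of directions turned with other settings, to 28 higher and 14 lower with median-of-ratios scaling, 17 and 10 with limma-voom and 28 and 23 with only the 2 groups compared. CD93 (chromosome 20, 23079360 to 23086324), a surface glycoprotein of myeloid and endothelial cells, fell from 13.7 ± 1.51 RPKM in WT to 0.0353 ± 0.0352 in the libraries labelled clone 1 and 0.0174 ± 0.0167 in clone 2 (SD, n = 3). Its changes were -6.70 (SE 0.32, limma adjusted p = 8.04e-06) and -6.88 (SE 0.32, limma adjusted p = 3.78e-05), and no alternative or left-out library ended either call. CD93 stood at -3.82 and -3.85 with a pseudocount of 1. PID1, an adaptor that binds phosphotyrosine motifs, rose from 26.1 ± 4.36 to 77.1 ± 10.6 and 78.9 ± 16.1 RPKM, by 1.56 (SE 0.20, limma adjusted p = 0.000635) and 1.58 (SE 0.20, limma adjusted p = 0.0201). SLITRK5, a transmembrane protein with leucine-rich repeats, rose from 14.2 ± 2.32 to 38.0 ± 6.66 and 42.5 ± 5.70 RPKM, by 1.41 (SE 0.19, limma adjusted p = 0.000904) and 1.58 (SE 0.19, limma adjusted p = 0.0201). IFITM3 rose by 0.78 (SE 0.17, limma adjusted p = 0.00877) and 1.38 (SE 0.17, limma adjusted p = 0.0201).

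SNRPC, the U1-C protein of the spliceosomal U1 particle, fell from 31.4 ± 4.83 RPKM in WT to 19 ± 2.24 in the libraries labelled clone 1 and 12.9 ± 1.13 in clone 2, with changes of -0.72 (SE 0.17, limma adjusted p = 0.0111) and -1.27 (SE 0.17, limma adjusted p = 0.0237). The clone 2 call of SNRPC ended with median-of-ratios scaling (limma adjusted p = 0.0717, with 0.184 the highest over all alternatives and left-out libraries). The clone 1 call of SNRPC ended without WT replicate 2 (limma adjusted p = 0.0527) and with median-of-ratios scaling (0.111 in limma). With a replicate block the clone 2 calls of SNRPC and IFITM3 were lost (limma adjusted p = 0.0894 and 0.0700). In clone 2 the calls of SLITRK5 and SNRPC were lost without any 1 WT or clone 2 library, with a limma adjusted p up to 0.132 for SLITRK5 (without clone 2 replicate 2) and 0.184 for SNRPC (without WT replicate 2). That of PID1 was lost without any 1 WT library or without clone 2 replicate 2 or 3 (up to 0.135 in limma, without WT replicate 2). PID1 also lost it without WT replicate 2 and clone 1 replicate 1 together (limma adjusted p = 0.0527). IFITM3 lost its clone 2 call without WT replicate 2 or 3 or any 1 clone 2 library (up to 0.153 in limma, without clone 2 replicate 2).

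The remaining 4 genes averaged under 1 RPKM and were named after their values were seen. B4GALNT3, which adds N-acetylgalactosamine to glycans, fell with changes of -3.12 (SE 0.38, limma adjusted p = 0.000583) and -3.15 (SE 0.38, limma adjusted p = 0.0201), IGF2BP1, an mRNA-binding protein, with -3.83 (SE 0.34, limma adjusted p = 0.000123) and -3.65 (SE 0.34, limma adjusted p = 0.00480), and MATK, a relative of the kinase CSK, with -1.52 (SE 0.30, limma adjusted p = 0.00511) and -4.23 (SE 0.30, limma adjusted p = 0.000940). S100A16, a calcium-binding protein, had 129 reads in WT and none in either clone, at least 20.2-fold lower in the libraries labelled clone 1 and at least 30.5-fold lower in clone 2 over the group. With a pseudocount of 1 B4GALNT3 stood at -1.50 and -1.53, IGF2BP1 at -1.33 and -1.31 and MATK at -0.89 and -1.61. With any 1 library left out MATK kept its clone 2 call, IGF2BP1 lost it without any 1 WT library (limma adjusted p up to 0.0725, without WT replicate 2), and B4GALNT3 and S100A16 without any 1 WT or clone 2 library (up to 0.135 and 0.131 in limma, without WT replicate 2). A replicate block ended the clone 2 calls of B4GALNT3 and S100A16 (limma adjusted p = 0.0700 for each). The count of 9 was 3, 2 and 2 without WT replicate 1, 2 or 3, 4, 3 and 3 without clone 2 replicate 1, 2 or 3, and 162 without clone 1 replicate 1. Both comparisons share the WT libraries. In 100 simulations with shared controls and no effect, no gene passed in both, but without an effect few genes can pass at all. Independent lists of these sizes would share 0.872 higher and 2.06 lower genes, against 3 and 6 observed, a figure that leaves out the shared WT libraries. Neither shows how far the shared WT libraries raise the overlap.

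**Figure D3:**
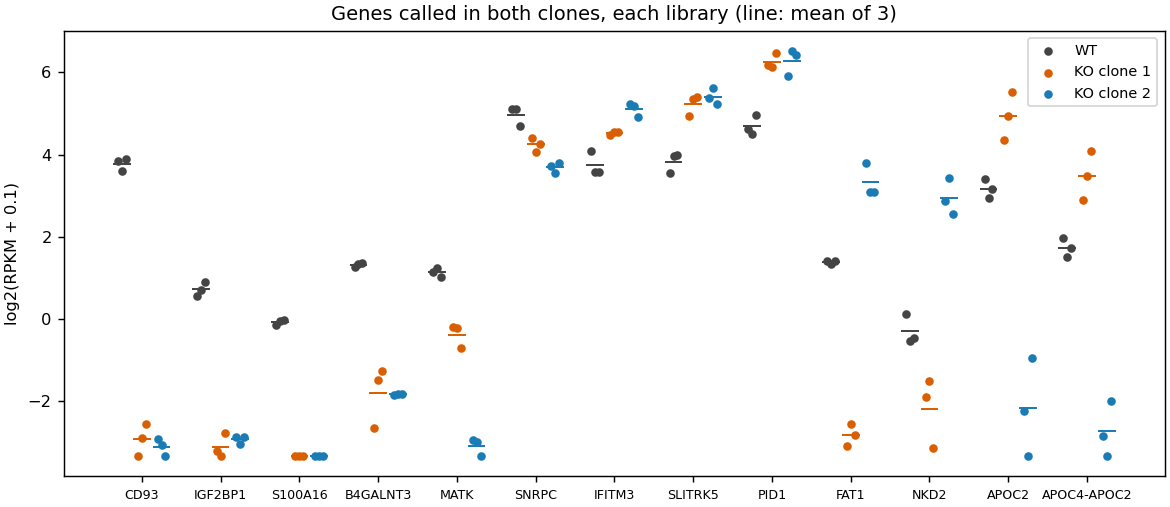
Expression as log2(RPKM + 0.1) of 13 genes past the test in both clones, 1 point per library in WT, clone 1 and clone 2, with a line at the mean of 3. CD93 lies at 13.7 ± 1.51 RPKM (SD, n = 3) in WT and at 0.0353 ± 0.0352 and 0.0174 ± 0.0167 in the clones.

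Another 4 genes passed in both clones in opposite directions, and were named after their values were seen. FAT1, an atypical cadherin, fell in the libraries labelled clone 1 with a change of -4.22 (SE 0.28, limma adjusted p = 2.64e-05) and rose in clone 2 by 1.93 (SE 0.28, limma adjusted p = 0.0434). NKD2 fell with a change of -1.90 (SE 0.45, limma adjusted p = 0.0116) and rose by 3.24 (SE 0.45, limma adjusted p = 0.0346). APOC2, the cofactor of lipoprotein lipase, rose by 1.77 (SE 0.53, limma adjusted p = 0.0329) and fell with a change of -5.34 (SE 0.53, limma adjusted p = 0.00678); the read-through gene APOC4-APOC2 covers all of its exons. With a pseudocount of 1 FAT1 stood at -1.76 in the libraries labelled clone 1 and APOC2 at -3.09 in clone 2. NKD2 then stood at -0.60 in the libraries labelled clone 1 and no longer passed (limma adjusted p = 0.0590). The clone 2 calls of FAT1 and NKD2 were lost without any 1 WT or clone 2 library, and that of FAT1 without clone 1 replicate 3 also (limma adjusted p up to 0.284 and 0.209, without WT replicate 2). They were lost as well with a replicate block (limma adjusted p = 0.137 for FAT1 and 0.0700 for NKD2) and without a filter on low values (0.0813 and 0.0657 in limma). APOC2 lost both calls without any 1 WT library, and its clone 1 call without clone 1 replicate 2 or 3 (up to 0.0588 in clone 2, without WT replicate 1, and 0.102 in clone 1, without WT replicate 2, in limma). The clone 2 call of APOC4-APOC2 ended without WT replicate 3 (limma adjusted p = 0.0507).

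SNRPC lay in a stretch of neighbouring genes on chromosome 6 that were low in clone 2. From 34587291 to 35091406 the 5 genes ILRUN, SNRPC, UHRF1BP1, TAF11 and ANKS1A had a median of -0.86 in clone 2. In each of the 5 every clone 2 library lay below every WT library. Without any effect chance gives such an order in 10% of genes, counting both directions. These genes were picked by their low clone 2 values, so the order is no added support. ILRUN stood at -0.79 (SE 0.22), UHRF1BP1 at -0.80 (SE 0.16), TAF11, a subunit of the transcription factor TFIID, at -0.95 (SE 0.21) and ANKS1A at -0.86 (SE 0.28). In the libraries labelled clone 1, TAF11 fell with SNRPC, with a change of -0.85 (SE 0.21, limma adjusted p = 0.0131), and so did ILRUN, with -0.82 (SE 0.22, limma adjusted p = 0.0208), a call lost without any 1 WT library (up to 0.0751 in limma, without WT replicate 3) and with only the 2 groups compared (0.0588 in limma). UHRF1BP1 stood at 0.38 (SE 0.16, limma adjusted p = 0.1) there and ANKS1A at 0.04 (SE 0.28, limma adjusted p = 0.928). The 16 genes on both sides had a median of -0.05 in clone 2, in a range from -0.85 to 0.31. The lowest of them, HMGA1, was as low as the stretch. In 3 of the 16 every clone 2 library lay below every WT library. The stretch was found by a scan of the clone 2 values, and its limits were chosen after they were seen.

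**Figure D4:**
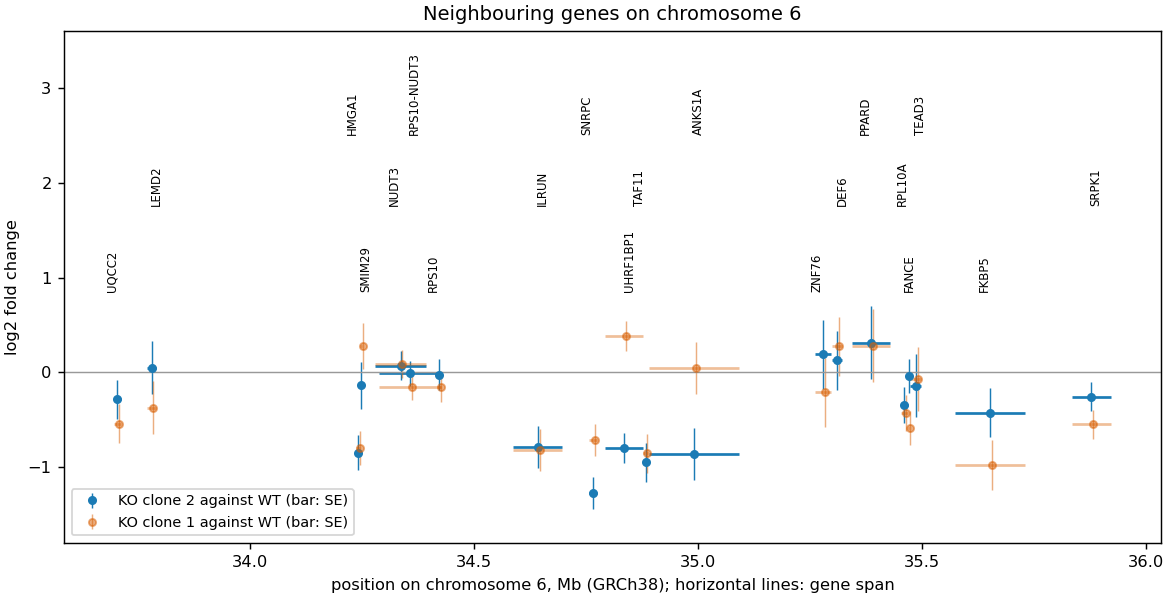
Log2 fold change against WT with its standard error of genes by position on chromosome 6 (GRCh38), 1 point per gene for clone 1 and for clone 2. In clone 2 the genes from ILRUN to ANKS1A lie between -1.27 and -0.79.

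The mean of both clones against WT tested the average of the 2 knockout lines, with p-values that cover the spread within clones. Mitosis genes fell and interferon-stimulated genes rose in this mean. Of 52 mitosis genes 41 fell, with a median of -0.87 (limma camera adjusted p = 1.91e-24; adjusted p = 0.294 with an estimated correlation), and 50 over the list alone. CDC20 fell with a change of -1.72 (SE 0.21, limma adjusted p = 0.00338), UBE2S with -1.13 (SE 0.13, limma adjusted p = 0.00317), CCNB1 with -1.27 (SE 0.16, limma adjusted p = 0.00338) and BIRC5, the chromosomal passenger survivin, with -1.36 (SE 0.19, limma adjusted p = 0.00496). Of 40 interferon-stimulated genes 13 rose and none fell, by a median of 0.83 (limma camera adjusted p = 6e-11; adjusted p = 0.468 with an estimated correlation), with 25 up and 1 down over the list alone. IFI6 rose by 1.57 (SE 0.23, limma adjusted p = 0.00579) and IFITM3 by 1.08 (SE 0.15, limma adjusted p = 0.00509). SAMD9L rose by 1.98 (SE 0.34, limma adjusted p = 0.01), a call lost without WT replicate 1 or 2 (limma adjusted p up to 0.0538, without WT replicate 1).

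S phase genes fell in 8 of 50, with a median of -0.65 (limma camera adjusted p = 4.96e-11; adjusted p = 0.593 with an estimated correlation), with 30 over the list alone. Ribosome biogenesis genes fell in 15 of 35, with a median of -0.51 (limma camera adjusted p = 1.71e-08; adjusted p = 0.294 with an estimated correlation) and 22 over the list alone. Oxidative phosphorylation fell in 6 of 28 genes, with a median of -0.43 (limma camera adjusted p = 9.09e-07; adjusted p = 0.504 with an estimated correlation) and 15 over the list alone, and cholesterol biosynthesis in 4 of 23, with a median of -0.63 (limma camera adjusted p = 1.95e-06; adjusted p = 0.613 with an estimated correlation) and 12 over the list alone. In clone 2 alone the medians were -0.07 for oxidative phosphorylation and -0.00 for cholesterol biosynthesis, against -0.72 and -1.24 in the libraries labelled clone 1. MCM7 fell with a change of -0.90 (SE 0.20, limma adjusted p = 0.0220) and FBL with -0.77 (SE 0.16, limma adjusted p = 0.0183). The call of MCM7 was lost without any 1 WT library or clone 2 replicate 2, and that of FBL without WT replicate 1 or 2 (limma adjusted p up to 0.108 and 0.0995, each without WT replicate 2).

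In the mean of both clones heterochromatin and DNA methylation genes fell in 8 of 24, with a median of -0.42 (limma camera adjusted p = 0.0124; adjusted p = 0.8 with an estimated correlation). HMGB2, a DNA-bending protein, fell with a change of -0.89 (SE 0.15, limma adjusted p = 0.00910) and HMGN2, a nucleosome-binding protein, with -1.31 (SE 0.22, limma adjusted p = 0.00932). Heat shock genes fell in 11 of 29 (-0.19; limma camera adjusted p = 0.0193; adjusted p = 0.251 with an estimated correlation), as did HSPD1, with -0.88 (SE 0.13, limma adjusted p = 0.00554), and the call of the list was lost without clone 1 replicate 3 (limma camera adjusted p = 0.234). DNA damage genes fell in 5 of 32 (-0.24, or -0.13 without WT replicate 2 and clone 1 replicate 1 together; limma camera adjusted p = 0.00752; adjusted p = 0.8 with an estimated correlation). XRCC6, a subunit of Ku, fell with a change of -0.69 (SE 0.15, limma adjusted p = 0.0220), a call lost with median-of-ratios scaling (limma adjusted p = 0.0530) and without any 1 WT library or clone 2 replicate 2 (up to 0.113 in limma, without WT replicate 2). Replacement variants fell in 5 of 10 and rose in 1 (-0.53; limma camera adjusted p = 0.00968; adjusted p = 0.468 with an estimated correlation). Clone 2 alone had medians of -0.17 for heterochromatin, 0.05 for heat shock, -0.23 for DNA damage and -0.11 for replacement variants.

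Linker histones (2.46; limma camera adjusted p = 0.000732; adjusted p = 0.251 with an estimated correlation), core histones (3.16; limma camera adjusted p = 7.45e-41; adjusted p = 0.251 with an estimated correlation) and non-coding RNAs (4.15; limma camera adjusted p = 1.32e-10; adjusted p = 0.251 with an estimated correlation) were higher in the mean, where clone 2 alone had medians of -0.90, -0.72 and -0.00. Without WT replicate 2 the non-coding RNA median of clone 2 was 0.90 and the list passed (limma camera adjusted p = 0.00327). The linker histone median in the mean was 1.34 without a filter on low values. In total 1901 genes passed, 1011 higher and 890 lower, and 4 passed when both clones were fitted as 1 group of 6. That count was 336, 365 and 449 without WT replicate 1, 2 or 3, 1015 without clone 1 replicate 2, 5255 without clone 1 replicate 1, and 947, 927 and 1224 without clone 2 replicate 1, 2 or 3.

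Clone 2 against the libraries labelled clone 1 tested where the lines differed. The non-coding RNAs RPPH1, RN7SK and RMRP, the RNA of ribonuclease MRP, were lower in clone 2, with differences of -11.63 (SE 0.94, limma adjusted p = 6.67e-05), -11.32 (SE 0.63, limma adjusted p = 1.26e-05) and -10.93 (SE 1.51, limma adjusted p = 0.00122). RN7SL3, a signal recognition particle RNA, differed by -10.29 (SE 1.23), RNY1, a Y RNA, by -10.04 (SE 1.47), H3C2 by -9.97 (SE 0.86), H1-4 by -9.62 (SE 0.70) and H4C13 by -9.61 (SE 0.92), all past the limma test. Within clone 2, RN7SL3 and RNY1 had reads in replicate 1 alone and H4C13 had 3 reads in all, so the sizes of these differences are uncertain. FAT1 was higher in clone 2 by 6.15 (SE 0.28, limma adjusted p = 7.28e-06), NKD2 by 5.13 (SE 0.45, limma adjusted p = 0.0001), the zinc finger gene ZNF43 by 4.54 (SE 0.29, limma adjusted p = 1.95e-05) and HOXB2, a homeobox transcription factor, by 3.46 (SE 0.52, limma adjusted p = 0.00172). HOXB-AS3, HOXB-AS1, ZNF486 and SLC12A7, a potassium chloride cotransporter, were higher by 3.75 (SE 0.61), 3.56 (SE 0.52), 3.57 (SE 0.30) and 3.41 (SE 0.43), all past the limma test. With a pseudocount of 1 FAT1 differed by 3.39, NKD2 by 2.93, ZNF43 by 1.87, ZNF486 by 1.60 and SLC12A7 by 1.60.

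Of the genes changed in both lines, CD93, PID1 and SLITRK5 gave clone differences of -0.18 (SE 0.32, limma adjusted p = 0.716), 0.02 (SE 0.20, limma adjusted p = 0.954) and 0.17 (SE 0.19, limma adjusted p = 0.554), which did not pass. IFITM3 differed by 0.59 (SE 0.17, limma adjusted p = 0.0347) and SNRPC by -0.56 (SE 0.17, limma adjusted p = 0.0371). Interferon-stimulated genes were higher in clone 2 than in the libraries labelled clone 1, by a median of 0.83 (limma camera adjusted p = 0.000557; adjusted p = 0.777 with an estimated correlation), and mitosis genes less low, by 0.57 (limma camera adjusted p = 5.37e-06; adjusted p = 0.777 with an estimated correlation). Cholesterol biosynthesis genes differed by 1.20 (limma camera adjusted p = 9.18e-07; adjusted p = 0.753 with an estimated correlation). In total 3694 genes differed, 2365 higher in clone 2 and 1329 lower, around a median of all genes of 0.22. With median-of-ratios scaling that median was 0.00 and 42.2% of the called genes were higher instead of 64.0%, the mitosis and cholesterol medians were 0.34 and 0.98, and the interferon median 0.64. The interferon median was 0.54 without clone 1 replicate 1 and 0.53 with a pseudocount of 1. The count was 5704 without clone 1 replicate 1, and 2177 and 2095 without clone 2 replicate 1 or 3.

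The lists that did not pass in either clone are given by their medians, clone 1 first. Polycomb group genes stood at -0.28 and 0.01, G1 cyclins and cyclin-dependent kinase inhibitors at -0.38 and 0.09, apoptosis regulators at -0.32 and 0.07, and glycolysis and hypoxia genes at -0.12 and -0.10. MHC class I presentation stood at -0.32 and 0.05, MHC class II at -0.42 and -0.09, NF-kB and inflammatory genes at 0.03 and 0.13, and HOX and stem-progenitor genes at -0.25 and 0.23, with 2 genes up and 7 down in the libraries labelled clone 1. Markers of other cell types or states were at -0.10 and 0.26 for neutrophils, 0.07 and 0.04 for erythroid cells, 0.28 and 0.50 for megakaryocytes and mast cells, 0.07 and 0.17 for lymphoid cells, and -0.41 and 0.74 for fibroblasts, endothelium and epithelium. In the libraries labelled clone 1, p53 targets (-0.34), monocyte markers (-0.04), heterochromatin (-0.51), DNA damage (-0.23) and heat shock genes (-0.49) did not pass, nor did linker histones (-0.90), replacement variants (-0.11), cholesterol biosynthesis and non-coding RNAs (both -0.00) in clone 2. Some of these lists passed in other settings. In the libraries labelled clone 1 heat shock genes passed with median-of-ratios scaling at -0.34 (limma camera adjusted p = 0.0473) and without clone 1 replicate 1 (0.00618 in limma). Heterochromatin, G1 and DNA damage genes passed without WT replicate 1 (0.0328, 0.0387 and 0.0311 in limma). Without a filter on low values these 4 lists and those of Polycomb, p53, erythroid and apoptosis genes passed there. In clone 2 linker histones passed without WT replicate 1 or 3 or clone 2 replicate 2 (0.0281, 0.0445 and 0.0287 in limma). Replacement variants passed without WT replicate 1 or clone 2 replicate 3 (0.0419 and 0.0353 in limma), and cholesterol biosynthesis without clone 2 replicate 3 (0.0483 in limma). No list passed with an estimated correlation in any comparison, the smallest limma adjusted p being 0.117, between the clones.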

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

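The values here are differences between clone 2 and the libraries labelled clone 1, drawn to attention because the test of the difference passed, and all tests of explanations in this part were chosen after the result was seen. Among linker histones, H1-2 differed by -5.82, H1-3 by -8.09, H1-4 by -9.62 and H1-5 by -9.33, all lower in clone 2. Of genes changed in both clones, IFITM3 differed by 0.59, SNRPC by -0.56 and MATK by -2.71. The core histone gene H2BC21 differed by -4.42 and the mitosis gene CDC20 by 1.19. The genes with opposite changes gave 5.13 for NKD2, 6.15 for FAT1, -7.11 for APOC2 and -6.20 for APOC4-APOC2. With a pseudocount of 1 NKD2 differed by 2.93 and FAT1 by 3.39. On chromosome 6, UHRF1BP1 differed by -1.19 and ANKS1A by -0.90.

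The list medians that differed were -6.95 for linker histones, -7.47 for core histones, -7.89 for abundant non-coding RNAs, 0.88 for replacement histone variants, 0.57 for mitosis, 0.47 for G1 cyclins and inhibitors, 0.67 for p53 targets, 0.42 for ribosome biogenesis, 0.83 for interferon-stimulated genes, 0.42 for apoptosis regulators, 1.20 for cholesterol biosynthesis and 0.58 for oxidative phosphorylation. None of them passed with an estimated correlation. With median-of-ratios scaling ribosome biogenesis stood at 0.19 and no longer passed, while mitosis stood at 0.34, G1 cyclins and inhibitors at 0.24, p53 targets at 0.44, apoptosis regulators at 0.19 and oxidative phosphorylation at 0.36. Without clone 1 replicate 1 the medians were 0.27 for G1 cyclins and inhibitors, 0.35 for p53 targets, 0.54 for interferon-stimulated genes and 0.13 for apoptosis regulators, and without clone 1 replicate 3 that of apoptosis regulators was 0.65. Calls were lost without 1 library for replacement variants (clone 1 replicate 3), ribosome biogenesis (clone 1 replicate 3 or clone 2 replicate 1), G1 cyclins and inhibitors (clone 1 replicate 2 or clone 2 replicate 3) and apoptosis regulators (WT replicate 1, clone 1 replicate 1 or 2, or clone 2 replicate 1), with a limma camera adjusted p of at most 0.193. The calls of G1 cyclins and inhibitors and of apoptosis regulators were also lost with the stricter filter (limma camera adjusted p = 0.0641 for each), and that of apoptosis regulators with only the 2 groups compared (0.0517 in limma). Linker histones stood at -2.97 without a filter on low values.

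The rise of histone mRNAs and of abundant non-coding RNAs in the libraries labelled clone 1 was weighed first. Scaling to totals that a few genes fill is argued against, since core histones kept a median of 7.08 with median-of-ratios scaling. In clone 2, where H1-3 reads were below WT, core histones did not rise as a group, with a median of -0.72, or -0.10 without WT replicate 2. Single members such as H2AC6 and H2BC12 stood above WT there, as given above. Core histones took only 0.00671% to 0.00996% of reads in clone 2, so a rise of RNAs without a poly(A) tail may be missed. Clone 2 therefore does not decide whether loss of H1-3 as such gives this pattern. A library preparation that keeps RNAs without a poly(A) tail may account for the rise. The 366 small nucleolar and Cajal body RNAs, of which 148 rose and 14 fell, had a median of 1.06 where over 2 was required, so this cause stays open. Preparation is confounded with the group, and a biological difference particular to this clone was not tested.

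The low genes around SNRPC were weighed next. Chance order is argued against, since 0 of 1000 random orders gave a window of 8 genes as low in clone 2. Reads shared between overlapping genes are argued against for the 5 low genes, where the highest shared part was 6.39% of exonic bases, and for the whole window, whose 3 of 8 genes that shared over 10% had a median of -0.0131 in clone 2. A lower copy number in both clones is argued against for the window, at percentile 64.0 of all windows in the libraries labelled clone 1, but not for the 5 low genes, at percentile 6.27 between the limits of 1 and 10. A loss of copies in clone 2 alone could give this pattern as well and was not tested, since no DNA data were used here.

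The interferon-stimulated and mitosis genes of clone 2 were weighed last. Scaling is argued against, since at least 94.8% of both medians was kept with median-of-ratios scaling. A WT library standing apart is argued against in the same way, with at least 91.5% kept without WT replicate 2. Loss of H1-3 is a candidate explanation that stays open. Interferon-stimulated genes had a median of 0.46 in the libraries labelled clone 1, whose RNA content differs and where H1-3 rose with other histone mRNAs. A difference between single cell clones unrelated to the edit was not tested.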

How the results depend on the processing

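The fits without WT replicate 2 and clone 1 replicate 1 together and the combined settings of the WT and clone 2 fit were chosen after the results were seen. The clone 2 count of 18 genes became 68 with median-of-ratios scaling, 54 with limma-voom, 28 with the stricter filter, 8 with a replicate block, 207 with only the 2 groups compared and 48 without those 2 libraries. In the fit of WT and clone 2 alone it was 170 with median-of-ratios scaling and 1 with a replicate block. Of the 18 genes, 17 were called again with median-of-ratios scaling, 18 with limma-voom and 18 with only the 2 groups compared. The 9 genes changed in both clones became 42, 27, 17, 5, 51 and 30 with the same 6 settings in the same order. The 1901 genes of the mean contrast became 3433 with median-of-ratios scaling, 2882 without those 2 libraries, 1004 with a 2-fold minimum and 4 with both clones as 1 group of 6. The 3694 genes that differed between clones became 2171 with only the 2 groups compared and 1832 with a 2-fold minimum, and the 4707 genes of clone 1 became 2511 with that minimum. The lists past camera in clone 1 went from 10 to 18 without a filter. By construction the libraries labelled clone 1 enter the spread used for clone 2 in the fit of all 9 and not in the fit of 6. For the other settings the cause was not tested.

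Leaving out 1 library at a time gave 2997 to 7252 genes for clone 1, 3 to 243 for clone 2, 2 to 162 for both clones, 336 to 5255 for the mean and 2095 to 5704 between clones. The lists past camera ranged from 9 to 13 in clone 1 and from 10 to 13 in clone 2. The H1-3 change ranged from 5.73 to 6.73 in clone 1 and from -2.36 to -1.35 in clone 2, where it was -0.81 with a pseudocount of 1, on the same side of the threshold in every setting run. H1-10 in clone 2 changed sign to 0.03 without WT replicate 3, 0.00 without clone 2 replicate 1 and 0.13 without clone 2 replicate 3, in a range from -0.19 to 0.13 over left-out libraries. ANKS1A in clone 1 changed sign to -0.10 without WT replicate 2, -0.08 without clone 1 replicate 2 and -0.11 without clone 1 replicate 3, in a range from -0.11 to 0.32, and the cause was not tested. Of the other values of named genes, 3294 stayed on their side of the threshold in the same direction, 252 no longer passed and 120 newly passed. Of list calls, 759 stayed, 32 no longer passed and 0 reversed; this was counted only for lists that passed in the comparison. Replicate numbers were not taken to pair the libraries, since 3 of 9 correlations of matched deviations were over 0.1. Against this, 6 of 9 libraries correlated best with one of their own number. The edgeR and DESeq2 fits named among the alternatives were not run. Whole reads were recovered and limma-voom was run on them, so the RPKM unit did not prevent such fits. Depth limits the H1-3 value of clone 2, which rests on 10 reads.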

Other observations

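The HOXB genes were split from the fixed HOX list, and the erythroid genes named, after their values were seen, while the counts of splits were planned. In the libraries labelled clone 1, 6 of 8 HOXB genes tested (chromosome 17, 48542656 to 48626358) fell, with a median of -2.57, and 6 had every library below every WT library. Without any effect chance gives such an order in 10% of genes, counting both directions. That share is no benchmark here, since 2825 of 15111 genes were called lower in these libraries and the HOXB genes were picked by their values. HOXB2 fell with a change of -3.28 (SE 0.52, limma adjusted p = 0.00180), HOXB6 with -2.55 (SE 0.38, limma adjusted p = 0.00133), HOXB7 with -3.05 (SE 0.46, limma adjusted p = 0.00141) and HOXB8 with -2.58 (SE 0.66, limma adjusted p = 0.0161). The call of HOXB8 was lost without WT replicate 3 or without clone 1 replicate 2 (limma adjusted p up to 0.0583, without WT replicate 3). HOXB7 stood at -1.99 and HOXB8 at -1.60 with a pseudocount of 1. In clone 2 none of the 8 passed, with a median of 0.21, and 7 differed between the clones. The 10 HOXA genes (chromosome 7, 27092995 to 27200091) had medians of 0.30 and 0.35 and 1 passed, HOXA6 at 0.92 (SE 0.26, limma adjusted p = 0.0267) in the libraries labelled clone 1.

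Of 6 erythroid markers tested 2 rose in the libraries labelled clone 1 and 3 lay below 0, with a median of 0.07, and the list did not pass (limma camera adjusted p = 0.193). The 2 that rose had few reads. HBA2, an alpha globin gene, had 114 reads there against 1 in WT, a ratio of 242 with a counting interval of 42.6 to 9651, and GYPB, glycophorin B, 33 against 1, a ratio of 70.1 with an interval of 11.7 to 2853. Clone 2 held 1 and 2 reads of these genes. On chromosome X, 8 neighbouring genes from ARMCX3 to NXF3 (101623130 to 103093143) had the highest window median in clone 2, 1.06, which 1 of 1000 random orders equalled, and some of them share exons.

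Other splits of the libraries were counted for each comparison. The splits of 3 against 3 number 10, too few for a share under 0.05. For clone 1, 1 of 10 splits gave as many genes, with 4707 in the real one and 0 in the highest other; for clone 2, 1 of 10, with 18 against 1; and between clones, 1 of 10, with 3694 against 8. For genes changed in both clones 5 of 100 splits gave as many as the real 9, the highest being 2882, and for the mean contrast 5 of 100 gave as many as the real 1901, the highest being 4642, so chance was not excluded. In both, the 4 other splits placed all 3 libraries labelled clone 1 in the reference group, which points to a structure of the samples. The highest of the remaining splits gave 7 and 691.

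Fold changes of the 2 clones correlated at 0.246 over 15111 genes, against 0.499 in simulations with shared WT libraries and no effect, and 64.1% of genes had the same sign against 66.6%. The covariance was 0.146 against 0.0693. The simulated covariance ranged from 0.0627 to 0.0760, so the observed one exceeded the mean that shared controls gave there by 0.0767. The WT libraries were not split between the clones to measure this part directly, and the source of the remainder was not tested.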
